A study of Mus musculus with 5 samples.

How the data were processed

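Single mouse cells of 3 types were profiled on 5 plates of 96 wells: 3 plates of ES R1 cells, 1 of Neuro2A and 1 of MEF, 480 wells in all. Per the labels' protocols, cells were sorted 1 per well, mRNA was reverse transcribed with a template-switching oligo whose 5-base barcode differed between wells, and the 96 reactions of a plate were pooled before PCR. Per the readme deposited with the series, the files hold raw hit counts, with 1 column per barcode and 1 row per feature. Bowtie is named in the submitters' processing notes. Its version, the genome build and the annotation are not given in the sources used here. The protocols name no molecular identifiers.

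The deposited counts were used as they are. Each file held 116 barcode columns, of which 96 had reads and 20 held only 0. Features were split by name into 15597 genes, 8654 repeats and 37 mitochondrial genes over the 5 plates, and each file listed only features with at least 1 read, so a gene absent from a file was taken as 0. Repeats took 26.1%, 82.4%, 40.0%, 24.6% and 23.02% of reads in ES replicates 1, 2 and 3, Neuro2A and MEF, and mitochondrial genes 9.28%, 2.44%, 8.45%, 12.9% and 10.96%. Both were left out of library sizes and tests. Predicted gene models (LOC and EG names), 1964 genes with 14.6% of gene reads, were kept. Gene names are those of the files.

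Wells with at least 1000 gene reads were kept. In order to respect that cells of a plate are not replicates, reads were summed over the kept wells of each plate. The 5 plate sums were fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, group means, TMM factors, filterByExpr, Benjamini-Hochberg at 0.05), with ES against MEF and ES against Neuro2A as contrasts. The fit had 2 residual degrees of freedom, all from the ES plates, and a common dispersion of 1.50, a biological coefficient of variation of 122%. Fits with 1 ES plate left out had 1 residual degree of freedom, and the simulations below did not cover them. CPM values are TMM-scaled. Folds against 0 reads used a floor of 3 reads per library, which is 0.242, 8.71 and 1.37 CPM in the ES plates (mean 3.44), 0.966 in Neuro2A and 1.52 in MEF. Intervals of 1 to 3 reads are exact 95% Poisson intervals. In bounded list medians, genes under the floor were set to it.

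The gene lists were pluripotency, extracellular matrix and mesenchyme, actin cytoskeleton, neuronal and neuroendocrine, early lineage differentiation, MHC class I and interferon-related, glycolysis, cell cycle and DNA replication, p53 and growth arrest, imprinted, immediate early and stress, oxidative phosphorylation, sex-linked and ribosomal proteins. They were tested with camera (limma 3.58.1, correlation preset at 0.01), with an estimated correlation and fry beside it, and the p-values were adjusted over the lists. Marker lists were ES, fibroblast, neuroblastoma, macrophage, endothelial, erythroid, primitive endoderm, neural progenitor, epithelial and muscle. All lists, tests and the alternatives listed first below were set before the data were examined.

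Neuro2A and MEF were compared by ratio, with list medians placed among 10000 random lists matched on mean expression. Genes were to be named by rule: 10 each way by log2 fold change among genes past edgeR's test, with every ES plate on the same side and at least 100 CPM in the higher group. For Neuro2A against MEF these were the 10 largest ratios of CPM + 1 each way at 100 CPM or more, and for variation the 10 highest mean residuals among genes read in at least 10% of cells of each ES plate. Members of the fixed lists could also be named. Some genes that met these terms are not reported here.

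For cells, reads were thinned to 1000 per well with a fixed seed. Clusters were k-means (scikit-learn 1.9.0, k = 3, 20 starts) on 10 principal components of the 1000 most variable genes, with Leiden (scanpy 1.11.5, leidenalg 0.10.2, 15 neighbours) as an alternative. Variation was the residual of the log squared coefficient of variation from its trend on the log mean. Shares of cells with a marker have exact binomial intervals, and the limit given beside a share of 0 is 3 cells of the total. Other steps used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

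Reads carried over between plates were sought after the data were seen. Genes with at least 100 CPM in a source plate and at least 10 times every plate other than source and target were compared between source and target at the same barcode, against 1000 permutations of wells, for 20 ordered pairs of plates, of which 4 lay above every permutation. For MEF to ES replicate 3 and Neuro2A to MEF, the median share per gene of the source's reads was subtracted, from the plate sums or, for cells, well by well. Both subtractions were made together unless the text names 1 of them. They removed 14.4% of the gene reads of ES replicate 3 and 9.71% of those of MEF. By construction they lower genes of the source in the target plate, so values after subtraction are not independent support.

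The steps were tested on simulated data. For ES against MEF with 12271 genes, 100 of them changed at each fold, edgeR recovered 1% of 4-fold and 12% of 16-fold changes at the fitted dispersion, with 6 false calls and 7 calls in an unchanged contrast. At a dispersion of 0.1 it recovered 36% and 84%, and at 0.01 84% and 90%. For variation (1942 genes), 100% of 103 changed genes were among the top. The mean correlation between plates was 0.145 with the changed genes and -0.0075 without variation. These counts were Poisson apart from the changed genes, so uneven copying by PCR was not covered. Neither correlation serves as a reference for the measured one. The carry-over search called 1 of 1 simulated copies and 0 of 2 controls. The barcode test (2113 genes) was called with 5% of reads copied, and not with none.

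The alternatives set beforehand were other scaling (RLE, library size only), other filters, DESeq2 1.42.0, limma-voom, all wells or those with 10000 reads, each cell weighted alike, fewer plates in the fit, each ES plate left out, and other thinning, gene numbers and clusterings. Chosen after seeing the data were the subtraction of carried-over reads, wells without barcodes ending in G, mitochondrial genes included, and leaving out the deepest well of ES replicate 2, or of each plate for repeat families.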

Results

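Single-cell transcriptomes of 3 mouse cell types were measured by tagged reverse transcription, in which each well of a plate carries its own barcode at the 5′ end of the cDNA and the wells are pooled before PCR. ES R1, an embryonic stem (ES) cell line labelled as embryonic stem cell-derived spheres, filled 3 plates. Neuro2A, a mouse neuroblastoma line, and mouse embryonic fibroblasts (MEF) filled 1 plate each. Every plate had 96 wells, and the stated design counts 436 single cells. Reads on genes numbered 11434036, 277068 and 2135379 in ES replicates 1, 2 and 3, 3160286 in Neuro2A and 2932933 in MEF. Wells with at least 1000 gene reads were kept, which left 93, 66 and 94 wells of the ES plates, 86 of Neuro2A and 92 of MEF, 431 in all.

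The median kept well held reads on 1521, 869 and 2087 genes in ES replicates 1, 2 and 3, on 1424.5 genes in Neuro2A and on 1668 in MEF. Depth differed widely between plates, from a median of 2520.5 gene reads per kept well in ES replicate 2 to 101130 in ES replicate 1. With every well thinned to 1000 reads, the medians were 399, 561.5 and 618.5 genes in the ES plates, 446.5 in Neuro2A and 520.5 in MEF. Wells whose barcode ended in G had more genes at that number of reads in every plate, by 23.9% in ES replicate 3 to 59.6% in ES replicate 1. Repeat families took 82.4% of all reads in ES replicate 2, against 23.02% to 40.0% in the other plates, and 1 well of that plate held 24.5% of its gene reads and 65.1% of the repeat reads of its kept wells. Intervals and floors given for reads cover counting error only, because PCR copies without molecular identifiers are not independent molecules.

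**Figure D1:**
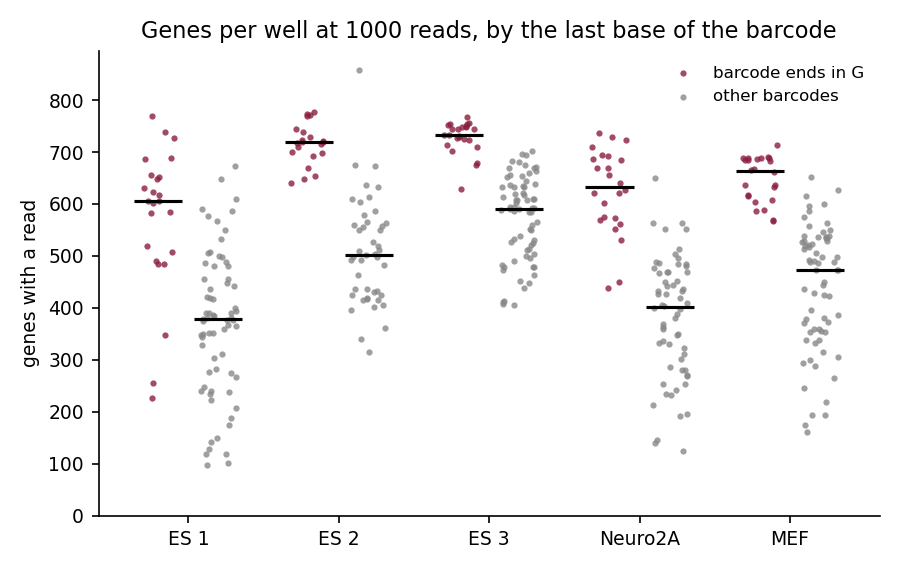
Genes with a read (vertical axis) in each kept well thinned to 1000 reads, by plate (horizontal axis), with wells whose barcode ends in G in red, other wells in grey and medians as black lines. The median was 605 against 379 genes in ES replicate 1 and 663.5 against 472.5 in MEF.

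Expression profiles of the 3 ES plates correlated only moderately with each other. Across 15597 genes, Pearson's r of log2(CPM + 1) was 0.658 between ES replicates 1 and 2, 0.760 between 1 and 3, and 0.638 between 2 and 3, with a mean of 0.686 ± 0.065 (SD over the 3 pairs). ES replicate 3 had an r of 0.736 with MEF, above 2 of those 3 values, while ES replicates 1 and 2 had 0.548 and 0.466 with MEF. Neuro2A had an r of 0.670 with MEF, also above 2 of those 3 values, and 0.647 with ES replicate 3, above the lowest of them. With ES replicates 1 and 2, Neuro2A had 0.610 and 0.516. Genes specific to MEF were present in ES replicate 3: over 200 such genes, the reads in ES replicate 3 came to a median of 10.8% of those in MEF, and they followed the MEF reads at the same well barcode. With that share subtracted from ES replicate 3, its r with MEF was 0.584, and 0.533 with Neuro2A reads also subtracted from MEF, although taking away a share of the MEF profile lowers this r by construction. Over genes of at least 10 CPM the ES pairs had 0.576, 0.644 and 0.540, ES replicate 3 with MEF 0.554, and the other pairs of different types at most 0.492. Spearman's rho of the same ES pairs was 0.651, 0.747 and 0.645. Genes are not independent replicates, so no test was made.

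**Figure D2:**
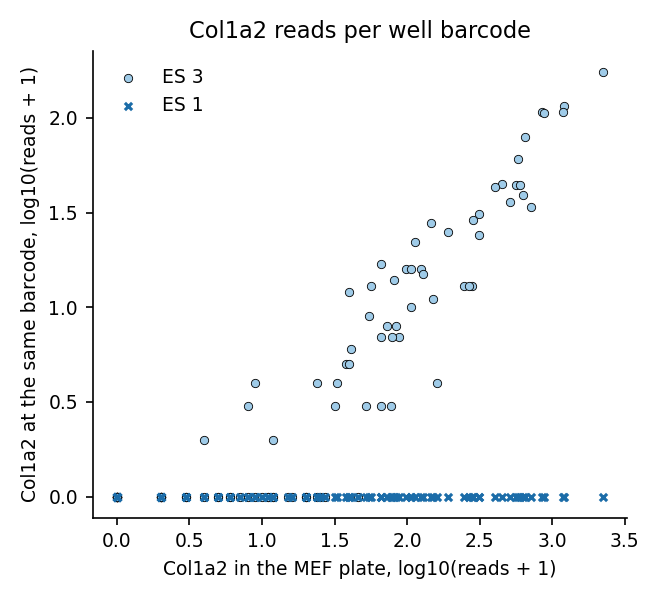
Reads of the collagen gene Col1a2 at each of 96 well barcodes, with the MEF plate on the horizontal axis and ES replicate 3 (circles) or ES replicate 1 (crosses) on the vertical axis, both as log10(reads + 1). At barcode number 1 the gene had 2231 reads in MEF, 174 in ES replicate 3 and 0 in ES replicate 1.

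The first comparison asked which genes distinguish ES cells from fibroblasts. Pluripotency genes were higher in ES, many of them with no read in MEF. Sall4, a zinc-finger factor of the stem cell network, reached 1242 ± 328 CPM (SD, n = 3) in ES and 0 reads in MEF, at least 820-fold higher. Dnmt3l, a cofactor of de novo DNA methylation, was at least 610-fold higher at 925 ± 226 CPM, and Zfp42 (Rex1) at least 499-fold higher at 756 ± 323 CPM. Nanog, at 444 ± 335 CPM, was at least 293-fold higher, and Pou5f1 (Oct4), at 98.2 ± 80.0 CPM, at least 64.8-fold higher. Sox2 had 2 reads in MEF and a ratio of 771 (counting interval 213 to 6365). Of 33 tested members of the list, 29 passed edgeR's test as higher and 0 as lower when adjusted over the list alone (adjusted p = 0.00184 for Sall4), and 0 passed over all genes (0.435 for Sall4). DESeq2 called 28 of them over all genes. The median member was higher by 6.46 on the log2 scale with genes at 0 set to the 3-read floor, and 31 members had every ES plate above MEF, where chance gives 25% each way.

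**Figure D3:**
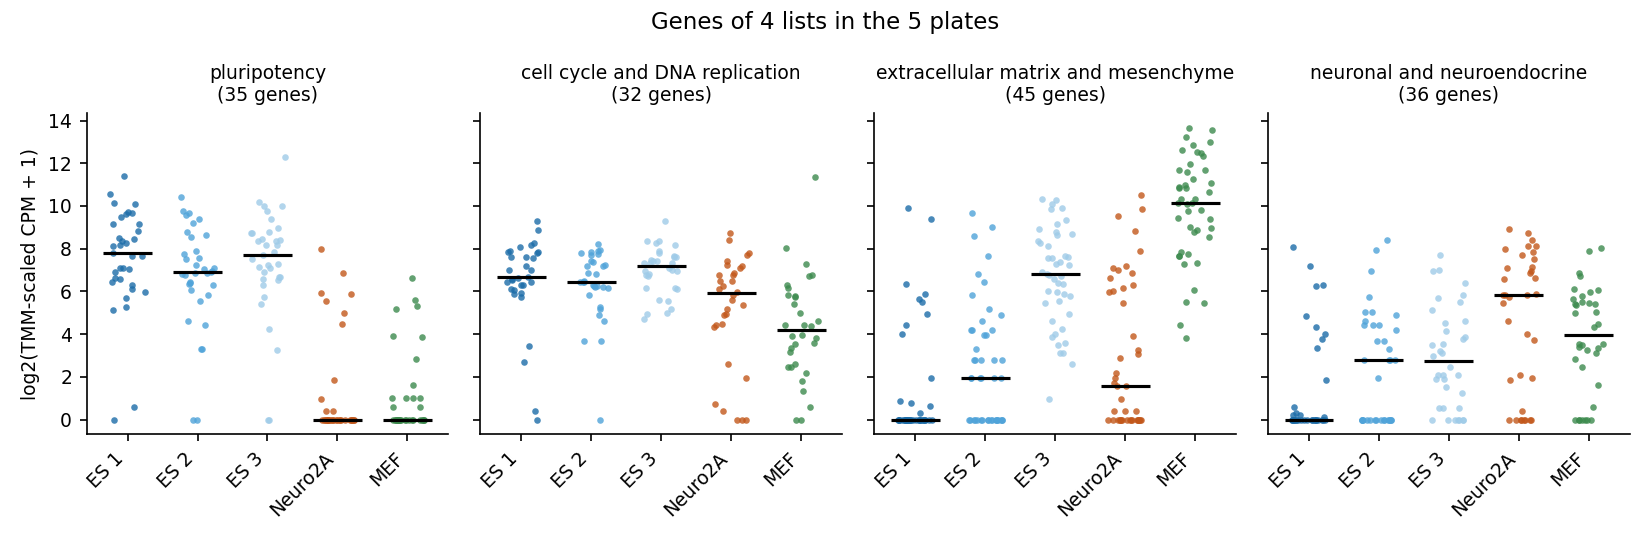
TMM-scaled expression, log2(CPM + 1), of the genes of 4 fixed lists (points) in the 3 ES plates, Neuro2A and MEF, with the median of each plate as a line. Pluripotency genes had medians of 222, 119 and 209 CPM in the ES plates and 0 in Neuro2A and MEF, and matrix genes a median of 1139 CPM in MEF.

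Genes of the cell cycle and DNA replication were also higher in ES than in MEF. Cdt1, which licenses replication origins, was at 217 ± 20.0 CPM in ES and 3.54 CPM in MEF, a 61.2-fold difference. Mcm3, a subunit of the replicative helicase, was at 230 ± 78.8 against 4.55 CPM, and Ccne1 (cyclin E1) at 104 ± 24.4 CPM against 0 reads, at least 68.3-fold higher. Of 32 members, 12 were higher in edgeR's test when adjusted over the list alone and 0 were lower. The list's bounded median was 2.89 on the log2 scale, and 5.16 with carried-over reads subtracted. With only MEF reads subtracted from ES replicate 3 it was 2.88, and with only Neuro2A reads subtracted from MEF 5.17. Taking reads from MEF raises this ratio by construction. The other called list with higher values in ES was glycolysis, with a bounded median of 1.12 and 0 of 18 members passing edgeR's test when adjusted over the list alone (3 at an unadjusted p under 0.05, 1 called by DESeq2). Camera gave it an adjusted p of 0.00642, and an adjusted p = 0.618 with an estimated correlation. Slc2a3, a glucose transporter, was at 486 ± 118 CPM in ES and 34.3 CPM in MEF, and Aldoa, an aldolase, at 1714 ± 972 against 264 CPM.

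Genes of the extracellular matrix and mesenchyme were lower in ES, with every ES plate below MEF for 45 of 45 members. Fibronectin (Fn1) was at 797 ± 121 CPM in ES against 5948 in MEF, vimentin (Vim) at 767 ± 332 against 7352, and Sparc, a matrix glycoprotein, at 607 ± 578 against 9732. The collagen gene Col1a2 had 0, 17.4 and 648 CPM in ES replicates 1, 2 and 3 against 8039 CPM in MEF, and thrombospondin (Thbs1) 0, 0 and 1079 against 12051. Much of the ES signal of such genes was in replicate 3, the plate with MEF reads at the same barcodes, and the bounded median moved from -4.82 to -7.10 on the log2 scale when these were subtracted, and to -7.14 with Neuro2A reads also subtracted from MEF. With edgeR, 0 of the 45 members passed when adjusted over the list alone, and 10 had an unadjusted p under 0.05. Without ES replicate 1, edgeR called 34 of them lower over all genes, and DESeq2 called 6.

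Actin and contractile genes were lower in ES, with a bounded median of -3.46 on the log2 scale (-4.08 after subtraction) and 4 of 26 members lower when adjusted over the list alone in edgeR. Filamin A (Flna) had a log2 fold change of -3.91 ± 0.68 (SE), vinculin (Vcl) -3.45 ± 0.65, thymosin beta 4 (Tmsb4x) -3.93 ± 0.90 and Myh9, a non-muscle myosin, -2.77 ± 0.66. Imprinted genes were lower, by a bounded median of -3.22 (-3.64 after subtraction), with 0 of 15 passing edgeR's test when adjusted over the list alone (4 at an unadjusted p under 0.05, 1 called by DESeq2). Gnas, a G-protein subunit, was at 1664 ± 933 CPM in ES and 16741 in MEF, and Igf2, a fetal growth factor, at 0, 0 and 348 CPM in ES replicates 1, 2 and 3 against 3057. Neuronal and neuroendocrine genes were lower as deposited, with a bounded median of -1.32. Reads of 133 genes specific to Neuro2A in MEF came to a median of 9.41% of those in Neuro2A and followed them at the same barcode. The bounded median was 1.20 with Neuro2A reads subtracted from MEF, and 1.18 with both subtractions. Both values lie at about the ratio of the 2 floors themselves, 3.44 CPM in ES and 1.52 in MEF. They do not show these genes as higher in ES, and camera's direction after both subtractions was still down. None of 29 members passed edgeR's test when adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 called 0. In that list Stmn2, a tubulin-binding protein, was higher in ES at 273 ± 67.6 against 54.5 CPM, and Gata3 was lower at 0.663 ± 1.01 against 62.6 CPM.

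The 7 lists described so far passed camera with a preset correlation between genes. The adjusted p-values were 7.85e-40 for pluripotency, 4.05e-19 for extracellular matrix, 1.98e-12 for actin, 1.45e-10 for cell cycle, 0.00138 for imprinted genes and 0.00991 for neuronal genes, with glycolysis as given above. None of the 7 held with a correlation estimated from the plates: the adjusted p with an estimated correlation was 0.435 for pluripotency and cell cycle, 0.757 for neuronal genes and 0.618 for the other 4. The neuronal call was lost after subtraction. By fry, which asks whether a list's genes move one way on balance, 0 lists passed, with an adjusted p of 0.155 for pluripotency.

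The remaining lists did not pass camera against MEF with the data as deposited. Bounded medians on the log2 scale were 0.13 for early lineage genes, -0.48 for MHC class I and interferon-related genes (1.11 after both subtractions), -0.78 for p53 and growth arrest, -1.31 for immediate early and stress genes, -0.68 for oxidative phosphorylation, -0.83 for the 3 sex-linked genes with reads and 0.06 for ribosomal proteins. The MHC value was -0.55 with only MEF reads subtracted from ES replicate 3 and 1.18 with only Neuro2A reads subtracted from MEF. As for neuronal genes, values of 1.11 and 1.18 lie at about the ratio of the ES and MEF floors. They do not show the MHC list as higher in ES, and camera's adjusted p after both subtractions was 0.865. For the MHC, p53 and sex-linked lists the mean of the fitted changes was positive and the median negative, and for early lineage genes the fitted median and mean were negative. Camera called ribosomal proteins higher in ES without ES replicate 2 (adjusted p = 0.00295), without ES replicate 3, without wells whose barcode ended in G, with mitochondrial genes and without the deepest well of ES replicate 2, and over 8 such settings its adjusted p ran to 0.353. As deposited, ribosomal proteins had an adjusted p of 0.757 with an estimated correlation and 0.835 by fry. It called early lineage genes lower only without ES replicate 3 (adjusted p = 0.0326, against 0.116 to 0.299 in the others, and 0.757 with an estimated correlation as deposited). Some members differed by a large ratio, but of those named here only Ifitm1 passed edgeR's test when adjusted over the list alone. Ifitm1, an interferon-induced membrane protein, was at 531 ± 181 CPM in ES with 2 reads in MEF, a ratio of 526 (counting interval 146 to 4342), and was the only member of its list that passed when adjusted over the list alone. B2m, the light chain of MHC class I, was at 130 ± 120 against 1800 CPM. Trp53 (p53) was at 242 ± 66.7 CPM in ES against 25.8 in MEF, and its target Cdkn1a at 104 ± 119 against 978. Myc was at 82.0 ± 47.1 against 602 CPM. Lama1, a laminin of the primitive endoderm, was at 55.1 ± 7.66 CPM against 0 reads, at least 36.4-fold higher.

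No single gene passed edgeR's test over all 12271 genes for ES against MEF, so the rule for named genes took none, and the genes above are members of lists fixed beforehand. At an unadjusted p under 0.05 there were 1028 genes. DESeq2 called 395 genes higher and 86 lower, and limma-voom 1 higher and 491 lower. Without ES replicate 1, the deepest plate, edgeR called 213 higher and 432 lower, against 0 without replicate 2 or 3. The p-values measure only the spread between these samples, which may be technical, since nothing says that the ES plates came from separate cultures, and the lone MEF plate was assumed to vary like them. Cell type and plate cannot be told apart here, and a fit without 1 ES plate had only 1 residual degree of freedom. The median gene differed by -0.08 on the log2 scale with TMM scaling and by 0.67 with library size alone. With TMM it was 0.34 without ES replicate 2, 0.46 without wells whose barcode ended in G and 0.60 after subtraction, so its sign depends on these choices.

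The second comparison asked which genes distinguish ES cells from neuroblastoma cells. Pluripotency genes were again higher in ES: Sall4 was at least 1287-fold, Dnmt3l at least 958-fold, Sox2 at least 806-fold, Zfp42 at least 783-fold and Tdgf1, a Nodal co-receptor, at least 724-fold higher, each with 0 reads in Neuro2A. Dppa5, an RNA-binding protein of pluripotent cells, was at 2835 ± 2108 CPM (SD, n = 3) in ES with 1 read in Neuro2A, a ratio of 8807 (counting interval 1581 to 347869). Of 33 tested members, 26 were higher in edgeR's test adjusted over the list alone and 0 were lower. The bounded median was 7.03 on the log2 scale, with every ES plate above Neuro2A for 29 members. Dnmt3b and Lin28, which belong to the same list, were not among the 26.

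Neuronal and neuroendocrine genes were lower in ES, with every ES plate below Neuro2A for 20 of 29 members and above it for 0. The granin Chgb was at 0.914 ± 1.58 CPM in ES against 232 CPM in Neuro2A, the synaptic protein Snap25 at 0.457 ± 0.792 against 122, and Elavl2, a neuronal RNA-binding protein, at 84.6 ± 33.8 against 490. The bounded median was -2.65 on the log2 scale and -2.67 after subtraction. In edgeR, 0 members passed when adjusted over the list alone and 9 had an unadjusted p under 0.05, while DESeq2 called 3 lower and 1 higher. In ES replicate 3, reads of 74 genes specific to Neuro2A came to a median of 1.78% of those in Neuro2A and were not subtracted. Outside the lists, Xlr3b and the neuroendocrine factor Insm1 had 0 reads in all ES plates. They stood at 252 and 164 CPM in Neuro2A, at least 73.3-fold and 47.7-fold higher, and were chosen after their values were seen.

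Further genes higher in ES than in Neuro2A came from several lists. The metallothionein Mt2 was at 1136 ± 230 CPM against 0 reads, at least 1177-fold higher, and Mt1 at 950 ± 364 CPM against 3 reads, a ratio of 984 (counting interval 337 to 4770). Trp53inp1, a p53-induced nuclear protein, was at 450 ± 110 CPM against 2 reads, a ratio of 699 (counting interval 194 to 5775). Ldhb, a lactate dehydrogenase subunit, was at 211 ± 89.1 CPM against 0 reads, at least 219-fold higher, and cyclin D3 (Ccnd3) at least 339-fold higher. Members of a list could lie on both sides: cyclin E1 (Ccne1) was at 104 ± 24.4 CPM in ES with 1 read in Neuro2A, while cyclin E2 (Ccne2) was at 8.23 ± 14.2 in ES against 427. Myc was at 82.0 ± 47.1 against 803 CPM, and H2-K1, an MHC class I heavy chain, at 55.3 ± 55.6 against 569. Midkine (Mdk) and osteopontin (Spp1), chosen after their values were seen, were at 480 ± 42.4 and 1015 ± 537 CPM in ES against 0 reads.

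Camera with a preset correlation called 6 lists against Neuro2A. The adjusted p was 3.44e-19 for pluripotency and 2.04e-07 for neuronal genes. It was 0.00886 for glycolysis (bounded median 2.11; 1 of 18 members, Ldhb, passed when adjusted over the list alone) and 0.0209 for cell cycle (1.21; 4 of 32, Ccnd3, Mcm5, Cdc6 and Ccne1). It was 0.0211 for p53 and growth arrest (2.26; 1 of 16, Trp53inp1) and 0.0404 for sex-linked genes (5.19; 1 of 3, Eif2s3y, Y-linked and at 0 reads in Neuro2A). For each of the 6 the adjusted p with an estimated correlation was 0.611, and by fry 0 lists passed, with an adjusted p of 0.184 for pluripotency. Without ES replicate 1, camera called 3 lists, losing cell cycle, glycolysis and sex-linked genes, and the sex-linked call was also lost after subtraction, without ES replicate 3 and without wells whose barcode ended in G. The cell cycle call was also lost with wells of at least 10000 reads, of which ES replicate 2 had only 2.

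The other 8 lists did not pass camera against Neuro2A with the data as deposited. Bounded medians of matrix, actin and imprinted genes moved with subtraction of MEF reads from ES replicate 3: extracellular matrix from 2.50 to -0.06 on the log2 scale, actin from 0.71 to 0.05 and imprinted genes from 3.09 to 1.02. Early lineage genes had a median of 3.15, with Otx2, Lama1 and Lamb1-1 passing when adjusted over the list alone, and MHC class I and interferon-related genes -1.83, with Ifitm1 and Ifitm3 passing. Immediate early and stress genes had 1.45, with Mt1, Mt2, Egr1 and Fosb higher and Myc lower. Oxidative phosphorylation stood at 0.07 and ribosomal proteins at 0.58. After subtraction, camera called extracellular matrix genes lower in ES (adjusted p = 0.0346, against 0.931 as deposited in the other direction, and 0.0617 to 0.954 over the other settings of plates and wells, and 0.983 with an estimated correlation as deposited). Without the deepest well of ES replicate 2 it called ribosomal proteins higher (adjusted p = 0.0422, against 0.0509 to 0.745 in the others). For ribosomal proteins too, the adjusted p with an estimated correlation was 0.983 as deposited. The MHC list had a positive mean of fitted changes, and camera's direction for oxidative phosphorylation was down.

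As against MEF, 0 of 12271 genes passed edgeR's test over all genes, with 1525 at an unadjusted p under 0.05. DESeq2 called 1077 genes higher in ES and 163 lower, and limma-voom 0. Without ES replicate 1, edgeR called 1016 higher and 422 lower, and without replicate 2 or 3 it called 0. The median gene was higher in ES by 0.91 on the log2 scale, so values above are to be read against that shift, which ran from 0.30 without ES replicate 3 to 1.76 with no filter on low counts.

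Neuro2A and MEF, 1 plate each, were compared without a test. MEF exceeded Neuro2A most in genes of the matrix. Tnc (tenascin C) stood at 5983 CPM in MEF against 0 reads, at least 6196-fold higher. Lox (lysyl oxidase) at 5707 CPM, the proteoglycan gene Bgn at 3039 and the collagen gene Col12a1 at 2958 also had 0 reads in Neuro2A. So did Pcdhg@ at 2835 CPM, Col8a1 at 2273, Prss23 at 1897 and Col5a2 at 1873. Pcdhg@ is a protocadherin cluster whose members share exons, so its value is uncertain. Thbs1 was 3404-fold higher (counting interval 1902 to 6819). Genes of the matrix list had a median log2 ratio of Neuro2A over MEF of -7.27, and 43 of 45 were higher in MEF. Actin genes had a median of -3.36, with 25 of 25 higher in MEF.

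Neuronal genes were higher in Neuro2A for 22 of 28 members, with a median log2 ratio of 2.46, and 4.59 with shared reads subtracted from MEF. Elavl2 was at 490 CPM in Neuro2A (counting interval 465 to 515) and 48.5 in MEF, and Chgb at 232 and 30.8, and both fell to 0 CPM in MEF after subtraction. Cell cycle genes had a median of 1.87 (2.94 after subtraction), with Ccne2 at 427 against 20.7 CPM and Mcm2 at 170 against 10.6, although cyclin D2 (Ccnd2) stood at 2657 CPM in MEF with 2 reads in Neuro2A. Among the genes with the highest ratios in Neuro2A, LOC668039, LOC100042109, 4930527E24Rik and Dqx1 stood at 124, 112, 108 and 106 CPM with 0 reads in MEF. EG245174 and LOC100039815 had 2 reads in MEF each, and ratios of 124 (counting interval 34.2 to 1030) and 108 (29.7 to 896). The others named by rule were Cep55, a protein of the midbody, 55.9-fold higher, Atpaf2, 53.4-fold, Zcchc18, 42.1-fold, and Slc6a15, a neutral amino acid transporter, 36.7-fold. The MEF reads of these 4 and of EG245174 and LOC100039815 were 0 after subtraction, so neither their ratios nor their order is settled. The LOC and EG models are predicted genes that may share reads with near-identical copies, and are uncertain.

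Set against 10000 random lists of matched expression, the medians of neuronal and cell cycle genes lay at percentile 100, and those of matrix, actin and imprinted genes at percentile 0. Imprinted genes had a median log2 ratio of -6.29, with Igf2 at 8.05 CPM in Neuro2A against 3057 in MEF and Grb10 at 0 reads against 1698 CPM. The p53 list had -4.14 (percentile 0.115), with Cdkn1a at 2.58 against 978 CPM, and early lineage genes -4.62 (0.81), with Dab2 at 3.86 against 539. The 8 pluripotency genes above 10 CPM had 2.35 (99.4; 4.26 after subtraction), with Dnmt3b at 256 against 38.4 CPM and Lin28 at 57.9 against 2.02, but Klf2 and Klf4 were higher in MEF, and the counting interval of Klf5 spanned equality. Medians were -1.53 for immediate early genes (3.55), 0.77 for MHC class I and interferon-related genes (92.9; 1.19 after subtraction), -0.54 for glycolysis (42.5), -0.71 for oxidative phosphorylation (20.5) and -0.44 for ribosomal proteins (37.8; -0.28 after subtraction). Of 3974 genes with at least 100 CPM in 1 of the plates, 212 were at least 8-fold higher in Neuro2A and 820 in MEF, and 1335 were within 2-fold. Without TMM scaling the split was 344 and 483, with subtraction 566 and 813, and with each cell weighted alike 190 and 429. The difference has no replicate check.

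At equal reads, cells grouped mostly by type without use of their labels. K-means with 3 clusters on 431 cells thinned to 1000 reads placed 90.7% of cells (exact interval 87.6% to 93.3%) in a cluster whose majority was their own type, where the largest type made up 58.7% of all cells. The interval treats cells as independent, which cells of a plate are not. With 1 plate each of Neuro2A and MEF, grouping by type cannot be told apart from grouping by plate. The ES-like cluster held 226 cells, all from ES plates, and had Dppa5, Tdgf1 and Sox2 as its leading genes. The fibroblast-like cluster, with Col12a1 and Tnc among its leading genes, held 79 MEF cells and 18 cells of ES replicate 3. The third cluster held all 86 Neuro2A cells with 13 of MEF and 9 of ES replicate 1, and had 0 neuroblastoma markers among its 10 leading genes, so it was left unnamed. Pcdha@, a protocadherin cluster, and Tmod2, a neuronal tropomodulin, led it. Leiden gave 7 clusters that also parted the ES plates, with 66 cells of ES replicate 1 alone in 1 of them, 69 of ES replicate 3 with 2 of replicate 2 in another, and 59 of ES replicate 2 with 1 of replicate 3 in another. With carried-over reads subtracted, all 94 cells of ES replicate 3 joined the cluster of the other ES cells. The share was then 97.4% of the 425 cells that still had 1000 reads, among them 86 of the 92 MEF cells. Taking a share of the MEF profile from ES replicate 3, and of Neuro2A from MEF, favours this rise by construction.

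**Figure D4:**
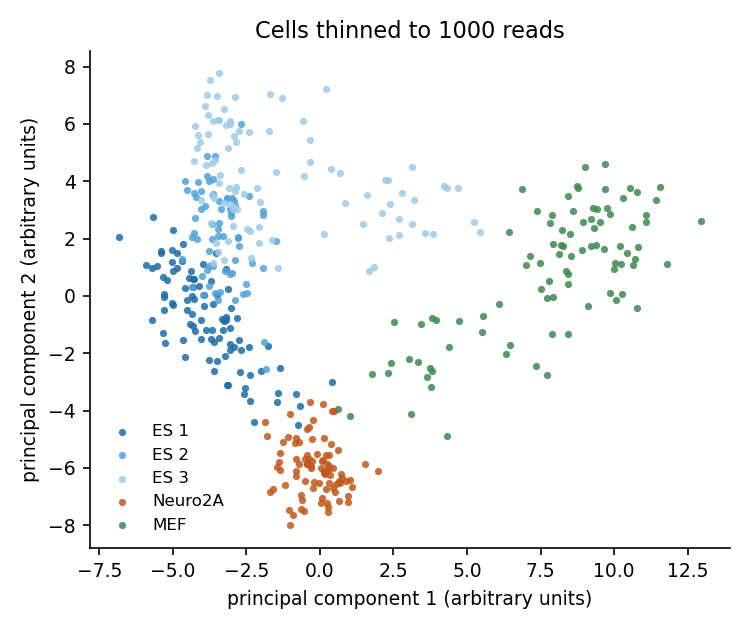
The first 2 principal components (arbitrary units) of 431 cells thinned to 1000 reads, with each point a cell colored by its plate. The groups of ES, Neuro2A and MEF cells separate in part, and 18 of the 94 cells of ES replicate 3 fell in the cluster of the 79 MEF cells.

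Markers of each type were read in most of its cells. With cells thinned to 1000 reads, at least 1 of 10 ES markers had a read in 92.5%, 93.9% and 96.8% of cells in ES replicates 1, 2 and 3. The same held for 1 of 92 MEF cells (1.09%) and 0 of 86 Neuro2A cells, which allows a share of up to 3.49%. Single markers were seen in fewer cells: Nanog had a read in 22.6%, 16.7% and 24.5% of cells of ES replicates 1, 2 and 3, and Pou5f1 in 6.45%, 1.52% and 12.8%. Fibroblast markers had a read in 98.9% of MEF cells, but also in 33.3%, 59.1% and 79.8% of cells of the ES plates and 47.7% of Neuro2A cells, and subtraction brought ES replicate 3 to 69.1%. In ES replicate 1 and Neuro2A few markers carried the share: Fn1 had a read in 29 cells of ES replicate 1, where Col1a1, Col1a2 and Lox had none, and in Neuro2A Fn1 and Fbln2 had a read in 21 and 22 cells. In ES replicate 3 all 12 markers were read, Sparc in 49 cells, Fn1 in 42 and Col1a2 in 29. Neuroblastoma markers had a read in 62.8% of Neuro2A cells, in 17.2%, 40.9% and 26.6% of cells of the ES plates and in 21.7% of MEF cells. Most of the ES share came from Stmn2, which had a read in 14, 23 and 15 cells of ES replicates 1, 2 and 3 (15.1%, 34.8% and 15.96%) in 17.4% of Neuro2A cells and in 1 of 92 MEF cells (1.09%). Unthinned, the share of cells with an ES marker was 100%, 98.5% and 100% in the ES plates. Shares of single markers depended more on depth: unthinned, Nanog had a read in 62.4%, 34.8% and 66.0% of these cells, and Pou5f1 in 46.2%, 7.58% and 57.4%.

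Markers of further cell types were mostly rare. Epithelial markers had a read in 20.4%, 37.9% and 19.15% of cells in ES replicates 1, 2 and 3, in 2.17% of MEF cells and in 0 of 86 Neuro2A cells. Primitive endoderm markers were seen in 4.30%, 4.55% and 12.8% of cells of the ES plates, 5.81% of Neuro2A and 26.1% of MEF cells. Neural progenitor markers were seen in 0%, 1.52% and 7.45% of cells of the ES plates, 4.65% of Neuro2A and 21.7% of MEF cells, and muscle markers in 1.08%, 0% and 0%, 3.49% and 13.04% in Neuro2A and MEF. Macrophage markers reached 6.06% of cells in ES replicate 2 and 2.13% in ES replicate 3, and 0% elsewhere. Endothelial markers were read in at most 1.52% and erythroid markers in at most 3.26% of cells of any plate. Unthinned shares were higher. Epithelial markers were then read in 54.8%, 43.9% and 62.8% of cells of the ES plates, and primitive endoderm markers in 57.6% of MEF cells. Macrophage markers were then read in 20.2% of cells of ES replicate 3.

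Genes differed in how much they varied from cell to cell within the ES plates, and the order was shared only in part. Across 759 genes, the residual of the squared coefficient of variation from its trend on the mean had a Spearman's rho of 0.301, 0.209 and 0.230 between plate pairs, a mean of 0.247 ± 0.048 (SD over 3 pairs). Gnas had the highest mean residual over the 3 plates, 1.74 ± 0.65 on the natural log scale (SD, n = 3), but not without ES replicate 1 (1.40, below Lars2 and Tpd52) or ES replicate 3 (1.78, below Tpd52, Aldoa and Cd81). It was followed by Tpd52 (1.65 ± 0.94), the aldolase Aldoa (1.32 ± 1.36), the RNA-binding protein Hnrpd (1.25 ± 0.23) and the tetraspanin Cd81 (1.24 ± 1.52). LOC545592, Rtn4, Tardbp, Lars2 and Gnl3, a nucleolar protein of stem cells, followed with 1.16, 1.15, 1.09, 1.09 and 1.09. Single cells weighed heavily: in ES replicate 1 a cell gave 178 of its 1000 reads to Aldoa, and the highest count of Gnas in a cell was 124. Without ES replicate 1 the mean residual was 0.74 for Aldoa, 0.46 for Cd81 and 0.63 for LOC545592, and without ES replicate 3 it was 2.06 for Aldoa, 1.98 for Cd81 and 0.04 for Lars2. In ES replicate 3 alone it was 3.18 for Lars2, -0.17 for Aldoa and -0.24 for Cd81. That plate holds reads that followed MEF and Neuro2A barcodes. Variation was not measured again with reads subtracted, nor without wells whose barcode ended in G. Whether carried-over reads raised residuals in ES replicate 3, such as those of Lars2 and Gnas, was therefore not tested.

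Housekeeping groups varied less than other genes of like expression. The median residual was -0.26 for 60 ribosomal proteins (percentile 0 among 10000 random lists) and -0.29 for 17 genes of oxidative phosphorylation (percentile 0.165). Glycolysis genes had -0.18 (5.43) and immediate early genes -0.18 (15.7), while pluripotency genes had 0.02 (68.7), actin genes 0.03 (64.8), cell cycle genes 0.09 (81.5) and MHC class I and interferon-related genes -0.06 (42.7). The remaining lists had fewer than 3 members with a read in 10% of the cells of every ES plate.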

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

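The tests of carried-over reads, of read numbers behind the excess of genes, of the deepest well and of genomic DNA were chosen only after the result was seen. Features outside the comparisons stood out in 3 places. Repeats took 82.4% of all reads in ES replicate 2, IAP elements 9.52% of the repeat reads of Neuro2A, and mitochondrial genes 12.9% of all reads in Neuro2A. They were picked out because these features were not used in the comparisons and these shares lay above those of the other plates. No biological explanation was tested for the patterns below.

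Genes of MEF appeared in ES replicate 3, where their reads followed those of MEF at the same well barcode, with a correlation of 0.659 against at most 0.0838 in 1000 permutations. Reads of the MEF library under the same barcodes are a candidate explanation, while feeder cells sorted into the plate would not follow the barcodes. ES markers made up at most 0.0454% of their ES level in MEF, which argues against even mixing of the libraries in both directions. The 9 genes specific to ES replicate 3 followed their barcodes in MEF (0.206 against at most 0.120) at a median share of 12.2%. However, the 10 ES markers had 3 reads in MEF against 19324 in ES replicate 3, which argues against passage to MEF at such a share. The 9 genes needed only to be lower in MEF than in ES replicate 3. A correlation at the same barcode does not tell the direction of passage. Neuro2A genes followed their barcodes in MEF (0.524 against at most 0.0750) and, less, in ES replicate 3 (0.327 against at most 0.0527). Where the reads crossed was not tested.

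Wells whose barcode ended in G held more genes at equal reads, by at least 23.9% in each plate, which argues against higher read numbers. A candidate explanation is template-switching oligos lacking 1 base, so that the first G after the barcode is read as its last base. Such wells correlated more with the wells whose barcodes could give theirs, by 0.0537 against at most 0.0223 in permutations, which a spread regardless of barcode would not give. By plate, the difference passed every permutation only in ES replicate 1 and Neuro2A. It was 0.0332 in ES replicate 3 and 0.0578 in MEF, under the highest permuted values of 0.0367 and 0.0627, and 0.0111 in ES replicate 2.

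The repeat share of ES replicate 2 was 69.4% without its deepest well, still above the highest other plate at 40.0%. Among wells of similar read number its median lay 15.1 points or more above the other plates, which argues against low depth as the whole cause, although only 3 wells of ES replicate 1 were matched and MEF wells ranged from 15.8% to 95.6%. Genomic DNA stays open. At 194529 gene reads and without its deepest well, the plate had 10183 genes, only 0.962% more than ES replicate 3 (10086). ES replicate 3 holds reads that followed MEF and Neuro2A barcodes, and the other plates had 7699 to 8875 genes. B2 elements made up 23.1% of the repeat reads of ES replicate 2 without that well. They made up 49.3% and 68.3% in the other ES plates, 50.5% in Neuro2A and 16.2% in MEF.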

How the results depend on the processing

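The alternatives with subtraction, without G-ending barcodes, with mitochondrial genes and without the deepest well of ES replicate 2 were tests chosen only after the result was seen. The number of genes called in ES against MEF was 9 without a filter, 481 with DESeq2, 492 with limma-voom and 0 to 645 when 1 ES plate was left out (645 without replicate 1). Against Neuro2A it was 82 without a filter, 1240 with DESeq2 and 0 to 1438 (1438 without replicate 1). The other alternatives called 0 genes. List calls fell to 0 with an estimated correlation and 0 with fry in both comparisons. Leaving out 1 ES plate gave 7 to 9 lists against MEF and 3 to 6 against Neuro2A (3 without replicate 1), and without the deepest well 7 lists were called against Neuro2A. Between Neuro2A and MEF, 619 genes were at least 8-fold apart with each cell weighted alike. The mean correlation of the ES plates was 0.587 for genes of at least 10 CPM. For depth and genes detected per well the mean of the medians was 3528 in wells of 10000 reads, where depth sets the value. ES replicate 2 had only 2 such wells. For the share of cells with a read of each marker, the value for any ES marker in ES cells was 99.5% unthinned and 87.8% for at least 2 reads. Cells in a cluster whose majority was their own type made up 71.2% when not thinned, 93.5% with k = 4, 93.7% with k = 5, 93.7% with Leiden and 97.4% after subtraction. When not thinned, no cluster had a Neuro2A majority. Of the Neuro2A cells, 64 then fell in a cluster with more ES cells, which also held 22 MEF cells, and 22 fell in another with more ES cells. The mean correlation of variation was 0.196 at 500 reads, and 0.214 to 0.293 over single plates left out. Of 1748 alternative values of named genes, 2 turned in sign: Eif2s3y in ES against MEF, 0.57 with each cell weighted alike, and Ddx3y, which ran from -3.62 to 0.37 (without ES replicate 2) when 1 ES plate was left out. Many named genes had 0 reads on 1 side or were picked for a large ratio, which left little room for a change of sign. The named ratios of Neuro2A to MEF did not turn in sign, but under alternatives set beforehand 80 values moved beyond their intervals and 70 did not (37 of 50 with each cell weighted alike, 36 of 50 without TMM), as did 15 of 50 after subtraction, and 2 values of variation moved. Except where depth is named, the cause was not tested. ES replicate 2, at a median of 2520.5 reads per well, limits what low genes can show.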

Other observations

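These comparisons were all chosen only after the result was seen, and no tests were made. Repeat families differed between plates. IAP elements, endogenous retroviruses, made up 9.52% of the repeat reads of Neuro2A against 0.231%, 0.773% and 0.224% in ES replicates 1, 2 and 3 and 1.45% in MEF. ETn elements were highest in the ES plates, with 1.76%, 0.508% and 0.828% against 0.146% in Neuro2A and 0.321% in MEF. B2 elements made up 49.3%, 11.9% and 68.3% of the repeat reads of the ES plates, 50.5% in Neuro2A and 16.2% in MEF, so the replicates differed widely. In ES replicate 2 a single well held 65.1% of the repeat reads, and without it B2 made up 23.1%. L1 elements, at 26.6%, and B1 elements, at 16.8%, took their highest shares in ES replicate 2, and stood at 20.7% and 13.9% without that well.

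Of the cells placed in a cluster of another type, 22 with Neuro2A and 18 with MEF, 0 came from a well whose barcode ended in G. Such wells were 24 of 93 kept wells in ES replicate 1, 24 of 94 in ES replicate 3 and 24 of 92 in MEF. At 1000 reads, the 9 cells of ES replicate 1 so placed had 97 to 239 genes, under the plate's lower quartile of 311. The 13 of MEF had 174 to 535 (lower quartile 380.5) and the 18 of ES replicate 3 had 448 to 697 (534.5).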
